A study of Homo sapiens with 2 samples.

How the data were processed

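RNA from CL1-0 cells, an established human lung adenocarcinoma line, was profiled on 2 Affymetrix expression arrays, 1 for cells given an antibody to FSTL1 for 0 h and 1 for cells given it for 6 h. Per the labels' protocols, total RNA was purified on silica columns and converted to biotin-labelled cRNA. The labels' treatment protocol also speaks of puromycin selection and stable transduction, with no vector named, and what was transduced is unknown here.

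The deposited values are probe set intensity on a linear scale, 54675 probe sets per array, as summarised by the authors. MAS5, the Affymetrix summarisation method, is named per the submitters' processing notes, with version and parameters not given in the sources used here. MAS5 combines the probes of a set after subtracting a local background and mismatch signal, so that dim values are noisy, and the arrays are then usually scaled to a common mean. Whether such scaling was applied is not stated. The mean without the top and bottom 2% of values was 256.4 at 0 h and 262.1 at 6 h, the lowest values were 4.58 and 4.34, and 1268 exact values occurred on both arrays. The scale between the arrays is therefore unknown, and differences below are on the values as given. A difference in scaling would move all genes together by a similar amount, and a background difference would move mainly dim genes.

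Probe sets were named through the platform's annotation, with symbols updated by Entrez gene identifier through a RefSeq gene table. Of the probe sets, 62 were array controls, 41097 had 1 gene, 1801 had several and 11777 had none. Of those with 1 gene, 41043 matched the RefSeq table by identifier. Probe sets with several genes or none were named for no gene. No coordinates are given because the annotation names no genome build.

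Values under the 50th percentile of the pooled values of both arrays, an intensity of 45.4, were set to that floor, which is an assumed background since no detection calls were used here. A probe set counted as measured when it was above the floor on at least 1 array (23274 probe sets of 12670 genes). Values were put on log2, a gene was represented by its probe set with the highest mean, and the difference was taken as 6 h minus 0 h. A gene at the floor on 1 array has only a bound, written as at least N-fold.

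Each group has 1 array, so there is no spread between replicates, no significance test and no replicate check of any difference. The number of arrays limits the precision. The only measure of error is the scatter between probe sets of the same gene, which are not replicates. Counts of genes at least 2-fold higher or lower were fixed before the data were examined, as were 34 gene lists. They cover FSTL1 and its partners, osteopontin receptors and proteases, integrins, immediate early genes, ERK output, NF-κB targets and cytokines, interferon-stimulated genes, and targets of BMP, TGF-β, YAP, p53, NRF2, ATF4, NOTCH and WNT. They also cover epithelial and mesenchymal genes, matrix proteases, G1/S and G2/M genes, histones, cholesterol and fatty acid synthesis, the unfolded protein and heat shock responses, hypoxia and glycolysis, clock and nutrient genes, the BCL2 family with caspases, cytosolic ribosomal proteins, the respiratory chain, reference genes, and markers of alveolar type II, fibroblast, leukocyte and endothelial cells. For a list with at least 5 measured members, the median difference was placed among the medians of 10000 random gene lists of the same size matched on mean log2 in 20 bins. A list was said to stand apart below the 1st or above the 99th percentile, as a description of these arrays. If genes varied independently, 0.68 of 34 lists would do so. Genes of a list can vary together and some lists share members, so this is no rate for repeated arrays. Counts at 1.5-fold were added after the data were seen.

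Genes to be named were fixed by rule before the data were examined. They are FSTL1 and SPP1, the 10 highest and 10 lowest differences among the brighter genes above the floor on both arrays whose other measured probe sets moved the same way, up to 5 genes each way whose several probe sets all passed 2-fold, up to 4 members of each list with the largest absolute difference, and up to 5 genes each way with the largest bound. Brighter means a mean log2 of at least 8.64, the median of genes above the floor on both arrays. Genes named outside this rule are said to be so.

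Alternatives were a floor at the 40th or 60th percentile, no floor or filter with log2(value + 16), differences centred on the median, quantile normalization, a loess curve of the difference on the mean (span 0.3), the median of a gene's probe sets, leaving out probe sets whose identifiers end in _x_at or _s_at, 10 bins for the random lists, and, added after the data were seen, lists without members that another list holds. The steps were tested on simulated data made from the values of both arrays. Differences were drawn independently from normal distributions with the spread of probe sets of like brightness. The counts that follow therefore check the steps and give no error rate for the real arrays. Of 12666 simulated genes, 25 that were not altered passed 1.5-fold and 0 passed 2-fold, and of 50 genes each planted 2-fold higher and 2-fold lower, 100% and 98% passed 1.5-fold. Of 200 simulated lists with no shift 4 stood apart, and of 50 lists shifted by 0.2 all 50 stood apart above. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.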

Results

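FSTL1 is a secreted glycoprotein of the follistatin family, and the experiment followed transcripts in CL1-0 lung adenocarcinoma cells given an antibody to it. The array at 0 h and the array at 6 h were compared, 1 array per time, so none of the differences below has a replicate check. Cells kept for 6 h with no antibody or with a control antibody were not analysed here, and the comparison therefore holds time in culture and handling together with the antibody. Median intensity over all probe sets was 45.8 at 0 h and 44.9 at 6 h, and 50.2% and 49.8% of probe sets lay above the floor.

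The question of the comparison is which transcripts differ after 6 h with the antibody. NR4A2, an orphan nuclear receptor of the immediate early class, was 2.59-fold higher at 6 h, from an intensity of 52.8 to 136.9, and its 3 measured probe sets had log2 differences of 1.04 to 1.38. Its 0 h value is close to the floor, and with the floor at the 60th percentile the difference was 0.92, under 2-fold. BCL6, a transcriptional repressor, was 2.27-fold higher (289.8 to 658.9). DDIT3, which encodes the stress transcription factor CHOP, was 2.01-fold higher (410.0 to 823.2). EPHB1, an ephrin receptor kinase, was lower (660.3 to 337.7), with log2 differences of -0.97 to -0.29 over its 3 probe sets. Most genes differed little: over 12670 genes the median log2 difference was 0.017, with an SD of 0.192 across genes.

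Genes at least 2-fold higher numbered 4, and 1 gene was at least 2-fold lower. Besides NR4A2, BCL6 and DDIT3 the higher group held GEM, a small GTPase (175.3 to 367.3), and the lower one was IFT46, a ciliary transport protein (123.7 to 51.8). GEM and IFT46 were chosen after their values were seen. At the smaller size of 1.5-fold, 95 genes were higher and 23 lower. The other probe set of BCL6 had a log2 difference of 0.40, and DDIT3 lay just under 2-fold under 3 other scalings, where 2 genes were 2-fold lower. With the floor at the 40th percentile 7 genes were 2-fold higher and 41 were 1.5-fold lower, and with it at the 60th percentile 0 were 2-fold lower and 10 were 1.5-fold lower.

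Among the brighter genes, JMJD1C, of the histone demethylase family, had a log2 difference of 0.95 (574.3 to 1109) and 3 probe sets between 0.64 and 0.95. The chromatin remodeller CHD2 was higher by 0.78 (602.5 to 1038), with 5 probe sets between 0.31 and 0.78. ETV1, an ETS transcription factor, differed by 0.77, with 4 probe sets between 0.05 and 0.77, and CCN1, a matricellular protein, by 0.71 (3303 to 5409). NFKBIA, the inhibitor of NF-κB, differed by 0.68 (778.0 to 1251), the mitochondrially encoded respiratory chain subunit ND6 by 0.66, and DDIT4, an inhibitor of mTOR signalling, by 0.64. ANKRD36B differed by 0.81, but it has near-identical paralogs that its probes cannot be assumed to separate.

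Among the bright genes that were lower, after EPHB1 came the N-acetylglucosamine kinase NAGK at -0.63 (770.5 to 496.4), the zinc exporter SLC30A1 at -0.57 (622.7 to 420.5), and UQCC3 and ZFTA, both at -0.54. ID1, an inhibitor of DNA-binding transcription factors and a BMP target, was at -0.51 (2924 to 2048). The ubiquitin ligase adaptors KCTD6 and KLHL9 were at -0.48 and -0.47, and the co-chaperone DNAJB1 was at -0.47 (1821 to 1314) with both of its probe sets lower. RNA45SN5, the multi-copy ribosomal RNA precursor, was at -0.62, with its other probe set at -0.15. The 5′ control probe sets of ribosomal RNA went opposite ways (18S -0.56, 28S 0.42), while their 3′ sets were both at 0.06. A fall of the precursor is therefore not shown.

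**Figure D1:**
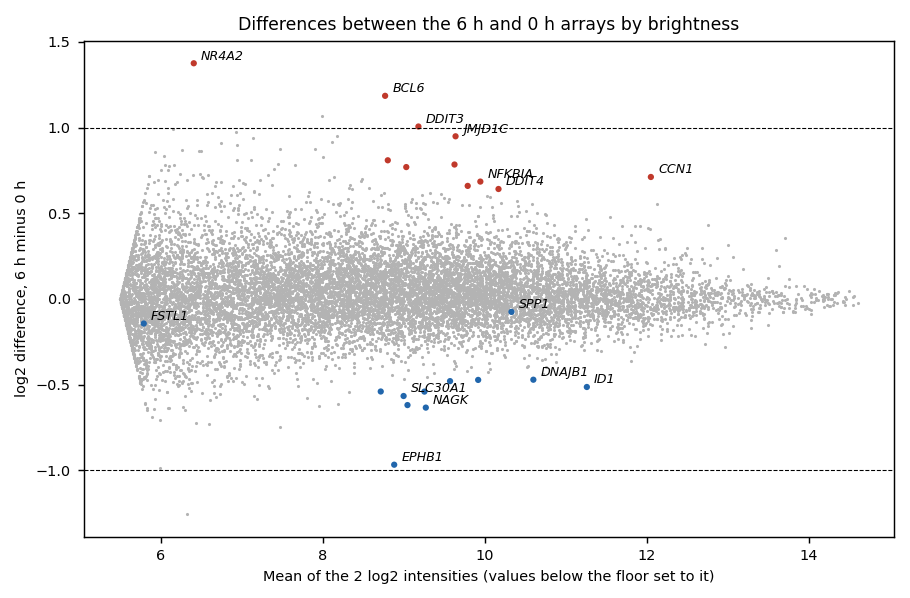
Each grey point is a gene, with the mean of its log2 intensities on the x axis and its log2 difference, 6 h minus 0 h, on the y axis; dashed lines mark 2-fold and coloured points are the named genes, red higher and blue lower. NR4A2, BCL6 and DDIT3 lie above the upper line, while FSTL1 (-0.14) and SPP1 (-0.08) lie near 0.

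**Figure D2:**
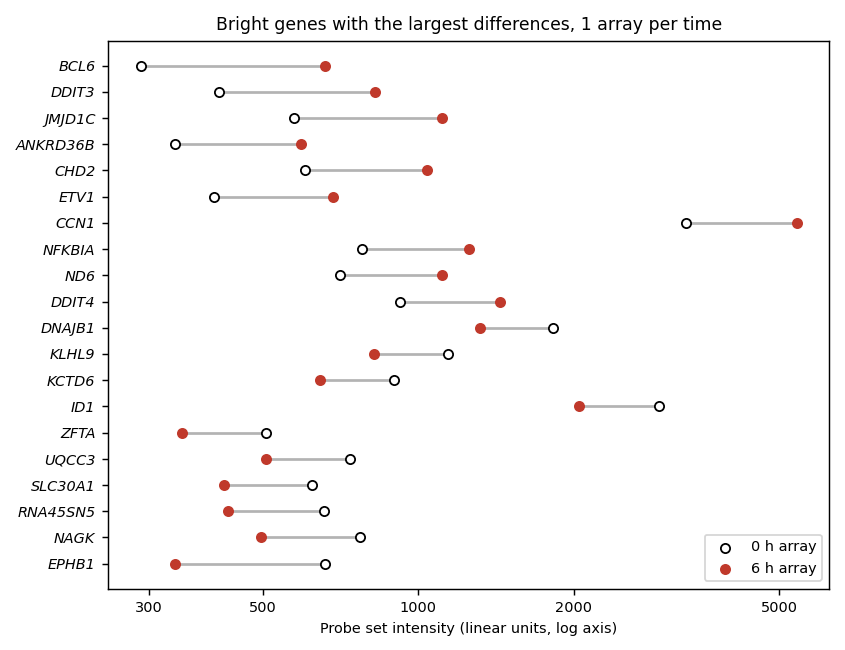
Intensity on the 0 h array (open circles) and the 6 h array (filled circles) of the 10 brighter genes with the highest and the 10 with the lowest difference, on a log axis, 1 array per time. CCN1 goes from 3303 to 5409 and EPHB1 from 660.3 to 337.7.

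A further set of genes passed the floor on 1 array alone and has only bounds, under the assumed floor. GDF15, a stress-responsive cytokine of the TGF-β superfamily, was at least 1.82-fold higher at 6 h. SLC2A12, KLRD1, JDP2 and HMCN1 were each at least 1.57-fold higher, with a second probe set of KLRD1 at a log2 difference of 0.22. The germ cell RNA-binding protein gene YBX2 was at least 1.98-fold lower, IL12RB1 at least 1.53-fold, ALX4 at least 1.52-fold, DYSF at least 1.44-fold and AIF1 at least 1.41-fold lower, and a second probe set of AIF1 differed by 0.01. These bounds depend on the floor: with it at the 60th percentile the log2 difference was 0.19 for GDF15 (0.86 in the main setting), 0.04 for SLC2A12 and KLRD1 (0.72 and 0.71) and -0.31 for YBX2 (-0.99), and the other 6 genes were no longer measured. With it at the 40th percentile KLRD1 (1.02), HMCN1 (1.02) and YBX2 (-1.04) passed 2-fold.

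The antibody's target and osteopontin, the secreted phosphoprotein encoded by SPP1, differed little in transcript level. FSTL1 itself was near the floor, at 58.3 and 52.8, with a log2 difference of -0.14, and of 500 genes of similar brightness 276 differed by as much. Its other 2 probe sets lay below the floor on both arrays (8.0 and 9.2, 25.9 and 30.0) and so have no direction here. SPP1 was at 1323 and 1256, a difference of -0.08. Among FSTL1 and its described partners, 7 of 13 were measured, with a median of -0.08 at the 13.2 percentile of random lists. Over the settings tried this median lay between -0.12 and 0.08, so its sign is not settled. BMP4 was the 1 member past 1.5-fold (74.6 to 49.7), on its only measured probe set and with a 6 h value close to the floor. DIP2A, a receptor for FSTL1, went from 548.7 to 733.1 but had 6 probe sets between -0.16 and 0.42. The osteopontin receptors and proteases (9 measured) had a median of 0.02 and the integrins (13 measured) one of 0.004. Transcript levels do not show whether the antibody blocked the protein.

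Genes of the immediate early response were higher together. Of 31 measured, 27 were higher and 4 lower, with a median of 0.25 at the 100th percentile of random lists. Next to NR4A2, the AP-1 family factors ATF3 and JUN went from 86.8 to 170.7 and from 67.2 to 122.0, and NR4A3 from 101.7 to 195.1. The second probe set of ATF3 differed by 0.30 and that of NR4A3 by 0.13. Genes of ERK output and feedback had a median of 0.36, with 13 of 15 higher, and one of 0.19 with no floor and no filter, which still stood apart. ETV5 went from 202.1 to 381.5, with 4 probe sets between 0.14 and 0.92. MAFF went from 515.7 to 792.1, the receptor kinase EPHA2 from 494.3 to 709.9, and the feedback inhibitor SPRY4 from 155.3 to 213.0.

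Targets of ATF4, the transcription factor of the integrated stress and amino acid response, had a median of 0.20, and 26 of 32 were higher. Besides DDIT3 and GDF15, the stress sensor SESN2 went from 208.7 to 403.1 with both probe sets at 0.95, and CHAC1, which degrades glutathione, from 93.2 to 163.7. In this list 7 members were at least 1.5-fold higher and 0 lower, but GDF15 and JDP2 among the 7 have only bounds. The 6 lower members, named after their values were seen, were GARS1 (-0.02), PSAT1 (-0.02), ASNS (-0.10), WARS1 (-0.16), ATF5 (-0.23) and EIF4EBP1 (-0.27). PHGDH (0.06), AARS1 (0.03) and SHMT2 (0.01), also named afterwards, differed little. Over the immediate early, ERK and ATF4 lists together, 63 of 75 members were higher.

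Sterol synthesis genes were also higher, with 0 members past 1.5-fold. Of 20 measured cholesterol genes 18 were higher, with a median of 0.26. The examples with the largest differences were the sterol carrier STARD4 (260.9 to 390.5), the synthase HMGCS1 (1445 to 2033), ACAT2 (2525 to 3523) and FDPS (3313 to 4449). All 10 measured fatty acid synthesis genes were higher on their brightest probe set, with a median of 0.19 at the 99.7 percentile. Among them were ACSS2 at 0.32, FASN at 0.30, ACLY at 0.24 and SCD at 0.23. However, FASN and SCD also had probe sets that were lower (-0.07 and -0.22). So did ELOVL5 (-0.28), ACACA (-0.26) and LPIN1 (-0.007), named after their values were seen. The fatty acid list no longer stood apart with the median of each gene's probe sets (0.06), or without _x_at and _s_at probe sets (0.14).

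Of 48 measured G2/M genes 38 were higher and 10 lower, with a median of 0.09, led by ECT2 (0.27), KIF23 (0.25), NDC80 (0.24) and KIF20B (0.23). p53 targets had a median of 0.14 at the 99.4 percentile, with 17 of 23 higher. They were led by SESN2, which the ATF4 list also holds, GADD45A (0.41), PPM1D (0.39) and TP53INP1 (0.35). The 6 lower members included CDKN1A (-0.26), AEN (-0.25) and TRIAP1 (-0.19), named after their values were seen. The p53 list no longer stood apart with the median of each gene's probe sets (0.03), or without members that another list holds (0.10). Its median was 0.21 without _x_at and _s_at probe sets.

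Heat shock genes were the 1 list that stood apart below. Of 17 measured, 15 were lower and 2 higher, with a median of -0.11 at the 0.03 percentile. DNAJB1 was the lowest, HSPA4L went from 179.5 to 137.8, and CRYAB from 58.2 to below the floor, while DNAJB4 was higher (485.0 to 674.5). In all 8 of the 34 lists stood apart, 7 above and 1 below, where 0.68 would do so if genes varied independently. Genes of a list can vary together and some lists share members, so chance differences between cultures are not excluded. Medians of all 8 kept their sign under every alternative tried.

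**Figure D3:**
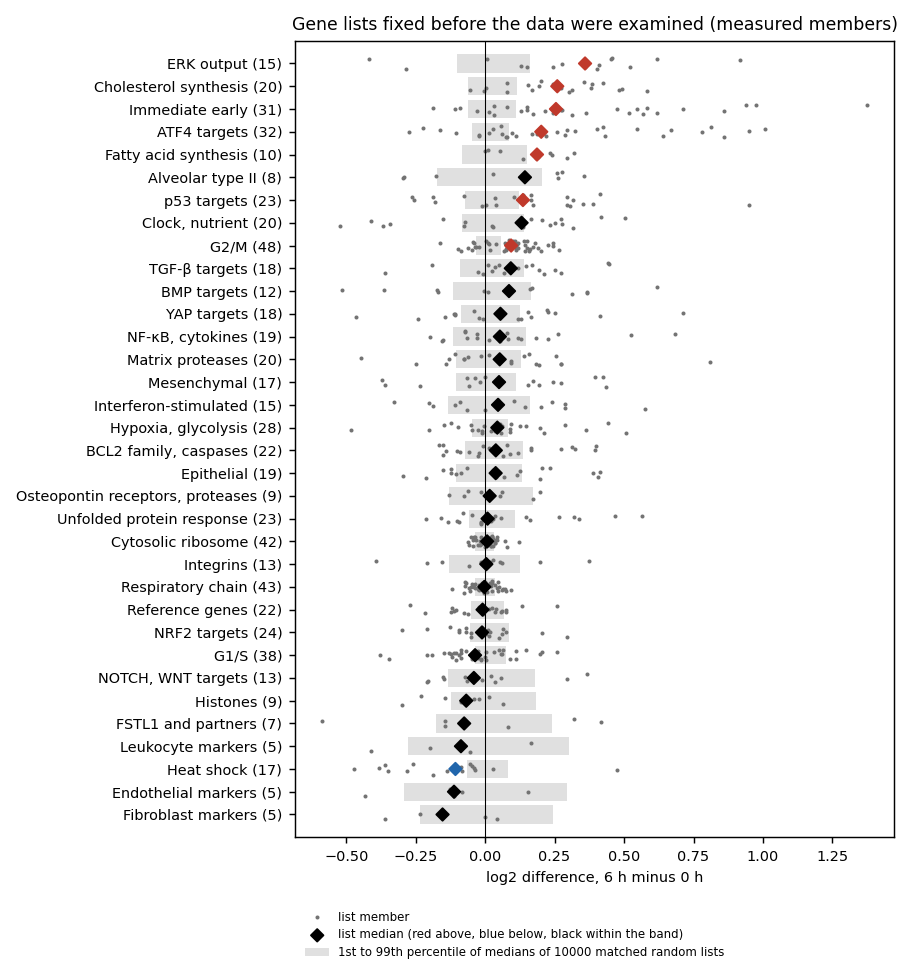
The x axis gives the log2 difference, 6 h minus 0 h. Each row is a gene list with its number of measured members, small points are members, diamonds are list medians and grey bars span the 1st to 99th percentile of medians of 10000 matched random lists; ERK output (0.36), cholesterol synthesis (0.26), immediate early genes (0.25) and ATF4 targets (0.20) lie above their bars and heat shock genes (-0.11) below theirs.

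The other 26 lists lay within the range of random lists. Among signalling targets, the median was 0.05 for NF-κB targets and cytokines (19 measured), 0.05 for interferon-stimulated genes (15), 0.09 for BMP targets (12), 0.09 for TGF-β targets (18), 0.05 for YAP targets (18) and -0.04 for NOTCH and WNT targets (13). Without _x_at and _s_at probe sets BMP targets stood apart at 0.31 with 5 measured, but this leaves out the only measured sets of ID1 and SMAD6. Members of one list went opposite ways: among BMP targets ID1 was lower while the inhibitory SMAD6 went from 101.8 to 156.4. ID2 (-0.17) and ID3 (-0.36), named after their values were seen, were also lower, while 7 of the 12 BMP targets were higher. NFKBIA and the subunit REL (374.2 to 537.9, 4 probe sets between 0.48 and 0.63) were the highest NF-κB genes, and LTBP1 (0.45) and SKIL (0.44) the highest TGF-β genes. COL1A1 had 2 probe sets that disagreed, at -0.36 and 0.94.

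Among structural genes, the median was 0.04 for epithelial genes (19 measured), 0.05 for mesenchymal genes (17) and 0.05 for matrix proteases (20). The desmosomal DSP and JUP were at 0.41 each, the mesenchymal factor ZEB1 at 0.39 (3 probe sets between 0.18 and 0.39) and the cathepsin CTSK at 0.81 (105.0 to 183.9). G1/S genes had a median of -0.04 (38 measured) at the 1.34 percentile, with CCNE1 (904.7 to 696.8) and the replication licensing factor CDC6 (1811 to 1425) lower and CDT1 at 0.26. Under quantile and loess scaling this list stood apart, with a median of -0.067 in each, as it did without _x_at and _s_at probe sets (-0.050). Mesenchymal genes stood apart with either other floor and with none (0.071 to 0.198). Histones had a median of -0.07 (9 measured).

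For stress and metabolism the median was 0.01 for the unfolded protein response (23 measured), 0.04 for hypoxia and glycolysis (28), -0.01 for NRF2 targets (24), 0.13 for clock and nutrient genes (20) and 0.04 for the BCL2 family with caspases (22). Clock and nutrient genes stood apart with the floor at the 60th percentile (0.15), and had a median of -0.01 without _x_at and _s_at probe sets. Within these lists the unfolded protein response factor XBP1 went from 538.9 to 796.3, HERPUD1 from 2066 to 2853, VEGFA from 1153 to 1637, FOXO1 from 62.5 to 88.6 and the clock repressor CRY2 from 193.3 to 134.7. Cytosolic ribosomal proteins (42 measured) had a median of 0.01, the respiratory chain (43) one of -0.003 and the reference genes (22) one of -0.01. Markers of alveolar type II cells, the cell type named in the labels, had a median of 0.14 (8 measured), which lay between -0.18 and 0.14 over the settings tried. Those of fibroblasts had a median of -0.15, leukocytes -0.09 and endothelium -0.11 (5 measured each). Most of these cell type markers were near the floor. Among the 26 lists the sign of the median was different under at least 1 alternative for 15, and was kept for NF-κB, TGF-β, mesenchymal, matrix protease, G1/S, histone, hypoxia, respiratory chain, reference, leukocyte and endothelial genes.

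Different probe sets of a gene scattered with an SD of 0.16 on the log2 scale, pooled over 6123 genes with at least 2 measured sets. Across these genes the differences of the brightest and the next brightest set had a Pearson correlation of 0.40 and a Spearman correlation of 0.39, where genes are not independent replicates. Of 49 genes past 1.5-fold with several sets, 39 had all sets moving the same way, against 3138 of all 6123. The 3′ to 5′ ratio was 1.14 and 1.12 for GAPDH and 1.68 and 1.72 for ACTB at 0 h and 6 h, and the 18 hybridisation spikes had a median difference of -0.02 (range -0.15 to 0.14). The 18S ribosomal RNA control differed more, with a 3′ to 5′ ratio of 1.54 at 0 h and 2.35 at 6 h.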

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

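The counts at 1.5-fold, the comparison of unnamed probe sets with random sets, and the split of brighter genes under quantile or loess scaling were chosen after the data were seen. So was the joining of the immediate early, ERK output and ATF4 target lists.

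A pair of observations lies outside the gene comparison. Probe sets with no gene name had a median log2 difference of 0.0293 over 3733 measured sets, against 0.0207 for those with 1 gene, and above all 1000 random sets of measured probe sets matched on brightness. Both medians are small in size. The SD of 0.16 between probe sets of a gene is for single sets and does not give the error of such medians. The random sets take probe sets as independent, which they are not. The 28S ribosomal RNA 5′ control probe set went from 5609 to 7492, a difference of 0.42, while the 5′ set of 18S went from 1996 to 1358.

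The immediate early, ERK output and ATF4 target lists were higher at 6 h, with a median of 0.25 over 75 members. The tables argue against an intensity-dependent scaling difference as the whole cause, since the median was 0.224 after a loess curve was taken off. The loess step adds little to the matching on brightness. Medians of matched random lists already centred on only 0.020 (immediate early), 0.023 (ERK output) and 0.015 (ATF4). The tables also argue against noise of dim probe sets as the whole cause. The 44 members of above-median brightness had a median of 0.217, where the 99th percentile of random lists was 0.08. Single faulty probe sets are argued against as well. The next brightest set of 39 members had a median of 0.217, where that percentile was 0.10. Time or handling without the antibody, for example a medium change, cannot be told apart from the antibody, because 0 arrays of cells kept 6 h without it were analysed. A response to the antibody may be the source but stays untested for that reason.

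Of the genes past 1.5-fold, 80.5% were higher at 6 h (95 against 23). Another scaling as the whole cause is argued against by a share of at least 71.3% under centring, quantile and loess scaling (77 of 108 at the lowest, exact 95% binomial interval 61.8 to 79.6, with genes taken as independent, which they are not). For genes of above-median brightness, noise of dim probe sets is argued against by 19 of 22, or 86.4% (exact interval 65.1 to 97.1). These 22 are a minority of the 118 genes past 1.5-fold, whose median intensity was 122.3 against 361.6 for all genes. For the dimmer majority such noise stays open. Scaling and noise together also stay open, since under quantile or loess scaling the brighter genes had 11 higher and 6 lower. A biological explanation was not tested, because antibody and time share 1 array.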

How the results depend on the processing

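Counts at 1.5-fold and lists without shared members were added after the data were seen. Of list medians under alternatives 320 stayed on their side of the thresholds, 8 came to stand apart and 4 no longer did; 0 reversed among those that stood apart. Immediate early (0.17 to 0.28), ERK output (0.19 to 0.38), ATF4 (0.15 to 0.28), cholesterol (0.20 to 0.26), G2/M (0.08 to 0.09) and heat shock (-0.12 to -0.09) medians stood apart under every alternative. Genes 2-fold higher numbered 7 with the floor at the 40th percentile. Genes 2-fold lower numbered 2 with that floor and with centring, quantile and loess scaling, and 0 with the floor at the 60th percentile or without _x_at and _s_at sets. Genes 1.5-fold lower numbered 41 and 10 with the floor at the 40th and 60th percentile and 11 with log2(value + 16). The mesenchymal median was 0.122, 0.198 and 0.0708 under these 3 settings and stood apart, as did clock and nutrient genes at 0.15 with the floor at the 60th percentile. G1/S stood apart at -0.0668 (quantile), -0.0667 (loess) and -0.0504 without _x_at and _s_at sets, where BMP targets, with 5 measured, stood apart at 0.31 and fatty acid genes no longer did at 0.14. With the median of a gene's probe sets fatty acid genes (0.0583) and p53 targets (0.0343) no longer stood apart, nor did p53 targets at 0.10 without shared members. The cause was not tested in these cases. Differences of named genes stayed on their side of 2-fold in 235 of 247 values, but most of these genes were under 2-fold to begin with. Only NR4A2, BCL6 and DDIT3 among them had passed it, and they fell under it in 6 values. These included DDIT3 (0.96 with quantile scaling), NR4A2 (0.92 with the floor at the 60th percentile) and BCL6 (0.79 with the median of its sets). In 6 other values a gene newly passed 2-fold, among them KLRD1 (1.02), HMCN1 (1.02) and YBX2 (-1.04) with the floor at the 40th percentile. Some lists had fewer than 5 members under stricter filters and gave no value. No paired analysis was possible because each time has 1 array. Signal near the floor limits the dim genes, where the floor sets the size of a difference.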

Other observations

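The tests of the zinc finger genes and of the mitochondrial ribosomal proteins were chosen after the values were seen, except that of their next brightest probe sets, and 12 gene families were looked at.

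Genes of the mitochondrial ribosome, which translates the respiratory chain subunits encoded in mitochondria, were lower at 6 h. Of 75 measured MRPL and MRPS genes 64 were lower, with a median log2 difference of -0.12, and the median lay between -0.14 and -0.06 under all settings tried. Among examples chosen after their values were seen, MRPL55 went from 1373 to 1086 and MRPS16 from 2017 to 1611, although the other probe set of each differed by -0.004 and 0.08. RNA polymerase subunits had a median of -0.05, with 23 of 30 lower, at the 0.53 percentile of matched random lists, and the median lay between -0.09 and -0.04 under the settings tried.

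One hypothesis is that the mitochondrial ribosomal protein genes move as a group, but the family was picked because it was low, so its median of -0.12 does not test this. The tables argue against scaling as the whole cause, since the median was -0.143 after loess. Loess adds little here, since medians of random lists matched on brightness already centred on 0.01. A like difference in all protein complexes is argued against by the cytosolic ribosome and respiratory chain lists, whose lower median was -0.00294. Transcript length was not compared, and most cytosolic ribosome genes were much brighter than the mitochondrial ones. A smaller difference shared with some complexes stays open, although the medians of proteasome subunits (-0.03, 23 of 35 lower, 4.49 percentile) and chaperonin CCT subunits (-0.03, 8 of 8 lower, 21.3 percentile) lay within the range of random lists. Single faulty probe sets cannot be told apart from a shared difference. Over 33 members the next brightest set had a median of -0.0515 where the 1st percentile of random lists was -0.051. By the rule set beforehand this goes against faulty sets, but the margin (0.995 percentile) is too small to decide.

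A hypothesis that zinc finger genes named ZNF with a number were higher as a group was not borne out, since 362 of them had a median of 0.00926 at the 9.34 percentile.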
